A study of Mus musculus with 2 samples.

How the data were processed

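Liver tissue of pooled B6NCrl mouse embryos of embryonic day 11.5 was assayed by ChIP-seq with an antibody to H3K27me3 in 2 biological replicates, with a fragment size range of 300 to 500 per the labels. The deposited files are 4 peak lists in narrowPeak format on build mm10. Per the notes deposited with the samples, the list of replicate 1 was made from 1 ChIP alignment and 2 control files, and that of replicate 2 from 1 ChIP alignment of 2 technical replicates and 1 of those control files. The pooled list was made from both alignments and both controls, and the replicated list was derived from the other lists. The aligner, the peak caller, their thresholds and the rule for a replicated peak are not given in the sources used here.

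Each peak has a position, a fold of ChIP over control, a −log10 p, a −log10 q and a score. The fold is a ratio deposited by the authors for the peak, not a value measured here. The −log10 values of p and q were likewise deposited by the authors, and the smallest −log10 p was 2.00 in the lists of replicate 1, replicate 2 and both together and 2.05 in the replicated list. The score in the deposited lists has a maximum of 1000 in each and was not used. Lists of different length rank peaks differently, so folds were tested only within a list, and those given for both replicates describe each list as called. The lists carry no read counts and no counting interval was computed, and the number of replicates, 2, limits the precision of every mean and SD.

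Peaks were compared with the mouse reference sequence GRCm38 and the GENCODE M21 annotation, which share the coordinates of mm10. All 85725, 34444, 54183 and 35986 peaks lay inside their chromosomes. Promoters were windows of 1000 bp on each side of the 5' end of 21911 protein-coding genes of chromosomes 1 to 19, X and Y. A promoter was marked if at least 1 bp of a peak lay in it. The replicated list gave the main value, and each replicate's own list gave the mean and SD. The fold of a named gene is that of the strongest peak in its promoter window, and its covered bp are those within 2500 bp on each side of the 5' end, a window of 5001 bp.

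Overlap between replicates was compared with 100 shuffles that moved each peak of 1 list within its chromosome and outside assembly gaps. The fold of shared and unshared peaks was compared by a 2-sided permutation test of medians with 100000 resamples. The 18 gene lists (16 typed by name and 2 families taken by symbol) were fixed before the data were examined and tested with 2-sided Fisher's exact tests against all other protein-coding genes. The p-values were adjusted by Benjamini-Hochberg at a false discovery rate of 0.05. Of the listed genes, 11 stand in more than 1 list. The imprinted list had 40 names, of which 34 matched a protein-coding gene. Domains were replicated peaks merged over gaps of up to 3000 bp. No second condition exists, so no test between conditions was made.

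Named genes followed a rule written before the data were examined. For each list it takes the 3 marked members with the largest mean covered bp over both replicates (ties by symbol) and up to 3 unmarked members with the lowest, and beyond the lists the genes with a 5' end in the 10 longest domains. Other genes named as marked or unmarked members of a list were chosen after their values were seen. Alternatives were a promoter window of 2500 bp, an overlap of at least 200 bp, peaks of −log10 q of at least 2, the pooled list, either replicate's list alone, 10000 random lists matched on promoter CpG content in 10 classes, 1 gene per 100000 bp stretch, an overlap of 50% of the peak, equal numbers of top peaks, and merging gaps of 1000 and 10000 bp.

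The procedures were tested on simulated data. With 59.5% of 34444 simulated peaks planted as shared, the overlap procedure recovered 59.4%. In 100 simulations over 21911 genes, 100% of lists planted at 80% marked were called and 1.67% of unchanged lists. Each gene was marked independently in these simulations, so the 1.67% does not apply to lists of neighbouring genes that share a domain. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.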

Results

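Trimethylation of histone H3 at lysine 27 (H3K27me3), the mark that Polycomb repressive complex 2 places on silent developmental genes, was mapped by ChIP-seq in liver of mouse embryos at embryonic day 11.5. At this stage the liver holds hepatoblasts, the progenitors of hepatocytes and bile duct cells, together with blood-forming cells, endothelium and mesenchyme. The embryos were of strain B6NCrl and of both sexes, and livers were pooled before chromatin was prepared, from 109 embryos in replicate 1. The series holds 1 group of 2 biological replicates, with 1 technical replicate in the first and 2 in the second, and no second tissue, age or treatment, so the comparisons are between replicates, between gene groups and between parts of the genome. The values are peak lists on mouse build mm10, 1 per replicate, 1 called on both replicates together and 1 of replicated peaks. The lists give no read number, so the depth of each library in reads is not known, and only a relative background level was fitted from them below.

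The peaks as called were many and narrow and covered a small part of the genome. Their widths belong to the calls, since the domain of the HoxC cluster described below was cut into 103 replicated peaks. The list of replicated peaks held 35986 peaks with a median width of 415 bp and a longest peak of 39484 bp, and it covered 32.7 Mb, or 1.23% of the ungapped genome. Replicate 1 had 85725 peaks over 41.0 Mb and replicate 2 had 34444 peaks over 23.0 Mb, a mean of 32.0 Mb ± 12.7 (SD, n = 2). Replicate 1 thus had 2.49 times as many peaks and 1.78 times as many covered bp. Its peaks were narrower, with a median width of 259 bp against 312 bp. The fold of ChIP over control per peak, the authors' own value, had a median of 3.36 in replicate 1 and 3.76 in replicate 2. With only peaks of −log10 q of at least 2, the lists held 51604 and 16700 peaks.

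Most peaks of the shorter list lay in regions called in both replicates. Of the replicate 2 peaks, 77.1% overlapped a replicate 1 peak by at least 1 bp, against a mean of 3.37% ± 0.0986 (SD over 100 shuffles) when the peaks were placed at random on their chromosomes. This is 22.9 times the shuffled share, and no shuffle reached the observed value (1-sided permutation p = 0.0099, the smallest that 100 shuffles can give). Moving each peak by 50 to 500 kb instead, a setting chosen after seeing the data, gave a mean of 9.23%, so that the observed share was 8.35 times that value. Of the replicate 1 peaks, 27.5% overlapped a replicate 2 peak, against 1.43% in shuffles with the same p. The regions covered in both lists made up 42.2% of those covered in either. Taking the 34444 strongest peaks of each replicate by −log10 p moved both shares, to 62.9% of replicate 2 peaks and 50.3% of replicate 1 peaks.

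Shared peaks were stronger and wider than unshared peaks within each list. In replicate 1, the median fold was 4.24 at 23538 shared peaks and 3.18 at 62187 unshared peaks, and the median widths were 510 and 233 bp. In replicate 2, the median fold was 4.01 at 26548 shared peaks and 3.29 at 7896 unshared peaks, with median widths of 375 and 221 bp. Both differences in fold had a 2-sided permutation p of 1.0e-05, the smallest that 100000 resamples can give. Peaks are not replicates, so these p-values describe the lists and not the animals.

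The replicated list was a subset of the list called on both replicates together and held 66.4% of its 54183 peaks. The kept peaks had a median fold of 3.53, and the 18197 others had 2.84. Of the kept peaks, 37.0% were overlapped over at least 50% of their length in both replicates' own lists, 44.6% only in that of replicate 1, 8.89% only in that of replicate 2 and 9.53% in neither. With 1 bp of overlap, 50.5% were overlapped in both. None of the 18197 peaks that were not kept met the 50% rule in both lists. A replicated peak in this series is therefore not always a peak of both single lists. The plot of marked promoters by gene list gives the share in each replicate for every list.

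Promoters in the lists of genes for embryonic patterning, some of which also stand in the liver lists, carried the mark in 87.5% to 100% of cases per list. Promoters of genes for basic cell functions almost never did. Among 21911 protein-coding genes, 4666 (21.3%) had a replicated peak within 1000 bp of the gene's 5' end. The share was 25.2% with the peaks of replicate 1 and 19.2% with those of replicate 2, a mean of 22.2% ± 4.21 (SD, n = 2). Of 18 gene lists fixed before the data were examined, 10 were marked more often than all other genes and 2 less often (2-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 18 lists). Genes of 1 cluster share a domain and are not independent, so these p-values describe the peak lists.

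The HOX genes, which set position along the body axis, were marked in full. All 39 had a replicated peak at the promoter, in each replicate as well, against 21.2% of other genes (Fisher's exact test, adjusted p = 3.4e-26). Hoxa3 (chromosome 6, 52169062 to 52213336, minus strand) and Hoxa7 (chromosome 6, 52214491 to 52221854, minus strand) had peaks across the whole 5001 bp around the 5' end in both replicates. The fold of the strongest promoter peak at either gene was 14.3 ± 0.988 (SD, n = 2). Hoxb13 (chromosome 11, 96194316 to 96197447, plus strand) was covered to the same extent, with a fold of 11.8 ± 0.922 (SD, n = 2).

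Transcription factors of the nervous system were marked at 42 of 42 promoters (Fisher's exact test, adjusted p = 4.8e-28), again in both replicates. Among them were Emx2, a regulator of forebrain development (chromosome 19, 59458372 to 59465357, fold 10.7 ± 3.03, SD, n = 2), Gsx2 of the ventral forebrain (chromosome 5, 75075601 to 75077893, fold 10.7 ± 2.73, SD, n = 2) and Irx3 (chromosome 8, 91798525 to 91802067, fold 11.3 ± 0.994, SD, n = 2). Transcription factors of pancreas, gut and lung were marked at 26 of 28 promoters (Fisher's exact test, adjusted p = 2.3e-15). The intestinal factor Cdx2 (chromosome 5, 147300805 to 147307270), the stomach factor Barx1 (chromosome 13, 48662998 to 48666507) and the thyroid factor Foxe1 (chromosome 4, 46343609 to 46346412) were covered over all 5001 bp in both replicates. Bhlha15, a factor of secretory acinar cells, and Isx, a factor of intestinal epithelium, had no peak within 2500 bp of the 5' end in either replicate.

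Transcription factors of heart, muscle and limb were marked at 32 of 36 promoters (Fisher's exact test, adjusted p = 2.5e-17). Foxc2 (chromosome 8, 121116171 to 121118895) had 4981 bp covered on average ± 28.3 (SD, n = 2) and a fold of 17.2 ± 0.909. Six2 (chromosome 17, 85684277 to 85688274) was covered over 5001 bp in both, although its fold was 15.9 in replicate 1 and 5.39 in replicate 2. The unmarked members were the muscle-determining genes Myf5, Myf6 and Myog together with Prrx2, while Myod1, the muscle factor of the same family, was marked. Signalling ligands of the Wnt, Fgf, Bmp and Hedgehog families were marked at 35 of 40 promoters (Fisher's exact test, adjusted p = 2.6e-18). Wnt10b (chromosome 15, 98770712 to 98778150, fold 11.5 ± 1.32, SD, n = 2), Wnt3 (chromosome 11, 103774150 to 103817957) and Wnt9a (chromosome 11, 59306928 to 59333552) were covered over 5001 bp in both replicates. Bmp5, Fgf4, Fgf7, Fgf10 and Fgf20 were the 5 unmarked ligands.

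**Figure D1:**
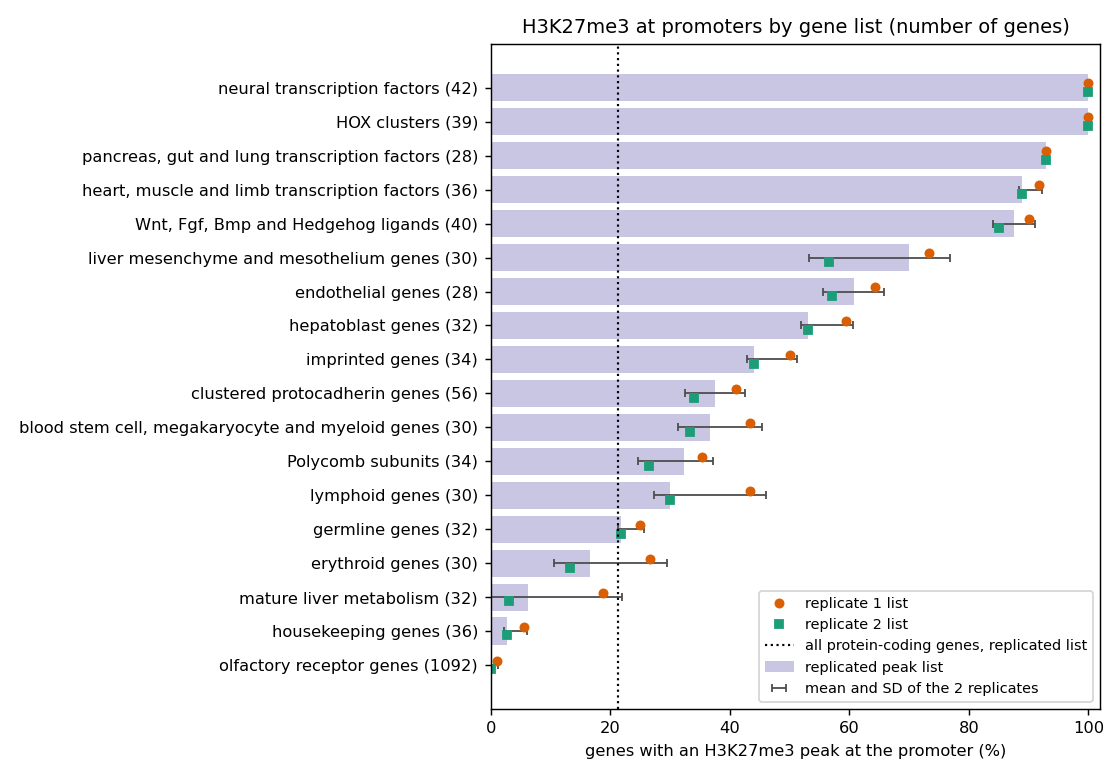
Percent of the genes of each list (number of genes in parentheses) with an H3K27me3 peak within 1000 bp of the 5' end. Bars give the replicated list, circles and squares the lists of replicates 1 and 2, whiskers the mean ± SD of the 2 replicates, and the dotted line the 21.3% of all protein-coding genes. HOX genes and neural transcription factors stand at 100%, housekeeping genes at 2.78% and olfactory receptor genes at 0.275%.

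Genes of the liver's own lineage were divided. Whole liver was assayed, so a peak at a gene of this list or of the blood and stroma lists cannot be assigned to any cell type. In the hepatoblast list 17 of 32 promoters were marked, more than among other genes (Fisher's exact test, adjusted p = 1.5e-04). The marked members included the liver-specifying transcription factors Foxa2 (chromosome 2, 148042877 to 148046969, 4879.5 bp covered ± 117, SD, n = 2), Onecut1 (chromosome 9, 74861921 to 74891781, 4853.5 bp ± 209) and Onecut2 (chromosome 18, 64340020 to 64400987, 4879.5 bp ± 172). The fold at Foxa2 was 10.5 in replicate 1 and 5.52 in replicate 2. Genes for proteins secreted into plasma were mostly unmarked: albumin (Alb, chromosome 5, 90460897 to 90476602), Apoa2 (chromosome 1, 171225054 to 171226379) and Apob (chromosome 12, 7977648 to 8016835) had 0 bp covered in both replicates. Splitting the list by product, a split made after the values were seen, gave 9 of 11 transcription factors marked and 1 of 14 plasma protein genes, which was Rbp4. No p is given for a split made from the values, and its classes were not matched on promoter CpG content. The 7 remaining genes, among them Cdh1, Epcam, Krt8 and Krt18 of epithelial cells, were all marked. The unmarked factors were Hnf1a and Hnf4a. Of the hepatoblast genes, 6 also stand in another list, 4 of them (Foxa1, Foxa2, Hhex and Onecut1) in that of pancreas, gut and lung.

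Genes of mature liver metabolism were marked at 2 of 32 promoters, with no difference from other genes past the threshold (Fisher's exact test, adjusted p = 0.062). The 2 were Ass1, an enzyme of the urea cycle (chromosome 2, 31470207 to 31520672), with 881 bp covered ± 297 (SD, n = 2), and Cyp1a2 (chromosome 9, 57676937 to 57683703), covered over 629 bp in replicate 1 and 0 bp in replicate 2. Abcb11, Adh1 and Aldob had 0 bp covered in both. The share was 18.8% with the peaks of replicate 1 and 3.13% with those of replicate 2, and the latter list alone gave an adjusted p of 0.0298 by the exact test.

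Blood cell lists were intermediate. Erythroid genes were marked at 5 of 30 promoters (Fisher's exact test, adjusted p = 0.698), namely Ank1, Tal1, Sptb, Slc4a1 and Hba-x. The share was 16.7%, against 26.7% with the peaks of replicate 1 alone and 13.3% with those of replicate 2. Ank1, a protein of the red cell membrane skeleton (chromosome 8, 22974844 to 23150497), had a fold of 12.5 ± 0.728 (SD, n = 2) around its annotated 5' end. The adult globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt and the erythroid factors Gata1 and Klf1 were unmarked. Genes of blood stem cells, megakaryocytes and myeloid cells were marked at 11 of 30 promoters (adjusted p = 0.062 by the exact test). Gp1bb, Gfi1 and Gata2 were covered over 5001, 4951.5 and 4918 bp on average, while the macrophage genes Adgre1, Cd68 and Csf1r had 0 bp. Lymphoid genes were marked at 9 of 30 promoters (Fisher's exact test, adjusted p = 0.296). The B-cell factor Pax5 (chromosome 4, 44524757 to 44710487) and the T-cell factors Bcl11b (chromosome 12, 107910403 to 108003602) and Tbx21 (chromosome 11, 97098071 to 97115331) were marked. Among surface receptor genes, Cd22, Cd4 and Cd79a were unmarked, and Cd3d and Cd3e were marked in both replicates. With the peaks of replicate 1 alone both the myeloid and the lymphoid list reached 43.3% (adjusted p = 0.0421 each, exact test).

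Genes of the stroma were marked more often than other genes. The endothelial list had 17 of 28 promoters marked (Fisher's exact test, adjusted p = 1.6e-05), with folds of 12.5 ± 1.55 at the VEGF receptor gene Flt1 (chromosome 5, 147561604 to 147726011), 12.4 ± 0.633 at Sox7 (chromosome 14, 63943673 to 63950732) and 12.0 ± 0.0149 at Sox18 (chromosome 2, 181669836 to 181671640; SD, n = 2 each). Cdh5, Egfl7 and Emcn, also endothelial, had 0 bp covered in both replicates. The list of liver mesenchyme and mesothelium had 21 of 30 marked (adjusted p = 3.6e-08 by the exact test), among them Foxf1 (chromosome 8, 121084386 to 121088144) and Wt1 (chromosome 2, 105126529 to 105173616), covered over 5001 bp in both replicates. Acta2, Col3a1 and Dcn had 0 bp covered, while Col1a1 and Des, for another collagen and another filament protein, were marked in both replicates.

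Housekeeping genes were marked at 1 of 36 promoters (Fisher's exact test, adjusted p = 0.0057, lower than other genes). The 1 gene was X-linked Pgk1 (chromosome X, 106187100 to 106203699), with 268 bp covered ± 53.7 and a fold of 3.28 ± 0.316 (SD, n = 2). Olfactory receptor genes were marked at 3 of 1092 promoters (adjusted p = 1.7e-109 by the exact test, lower), or 0.275%, against 22.4% of other genes and a mean of 3.37% in random lists matched on promoter CpG content (adjusted p = 4.5e-04, permutation). Of the 3 marked genes, Olfr558 had no peak in either replicate's own list. Clustered protocadherin genes, which code for neuronal adhesion proteins on chromosome 18, were marked at 21 of 56 promoters (Fisher's exact test, adjusted p = 0.0076). Against random lists matched on promoter CpG content, with a mean of 28.1%, the call was lost (adjusted p = 0.199, permutation). The marked ones were 19 members of the gamma cluster together with Pcdhac1 and Pcdhac2, and no other alpha and no beta gene was marked. Pcdhga11 (37755731 to 37841873) had 4509.5 bp covered ± 218 (SD, n = 2). Keeping 1 gene per 100000 bp stretch left 3 genes, of which 0 were marked (adjusted p = 1, exact test), too few to show whether the call holds without neighbours.

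The list of genes subject to parental imprinting was marked at 15 of 34 promoters (Fisher's exact test, adjusted p = 0.0048), with folds of 10.7 ± 2.42 at Ascl2 and 7.82 ± 1.92 at Grb10 (SD, n = 2 each). The fixed list also held the cell cycle inhibitor genes Cdkn2a (fold 10.3 ± 0.169, SD, n = 2) and Cdkn2b, which are not imprinted. Without them, a setting chosen after seeing the data, 13 of 32 were marked (adjusted p = 0.0223, exact test). Cd81, Ddc and Impact had 0 bp covered. Subunits and partners of the Polycomb complexes were marked at 11 of 34 promoters (adjusted p = 0.167 by the exact test). Epop, Cbx4 and Pcgf5 had 4220.5, 3692 and 3591 bp covered on average, and the core subunit Eed and the chromobox genes Cbx6 and Cbx7 had 0 bp. Germline genes were marked at 7 of 32 promoters (Fisher's exact test, adjusted p = 1). The pluripotency and germ cell factors Prdm14, Pou5f1 and Prdm1 had folds of 7.06 ± 2.62, 6.43 ± 1.26 and 6.88 ± 0.140 (SD, n = 2), and Dazl, Ddx4 and Figla had 0 bp covered.

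The longest domains of the replicated list lay over the HOX clusters. Merging replicated peaks less than 3000 bp apart gave 13360 domains, of which 958 were at least 10 kb long, and the 4 longest each held a HOX cluster. First place changed with the setting: with the peaks of replicate 1 alone the longest domain lay on chromosome X (99125586 to 99307300, 182 kb), as it did with a merging gap of 10000 bp (99152125 to 99692009, 540 kb). The domain of the HoxC cluster (chromosome 15, 102903094 to 103156051) was 253 kb long and held the 5' ends of Hoxc4, Hoxc5, Hoxc6, Hoxc8, Hoxc9, Hoxc10, Hoxc11, Hoxc12 and Hoxc13. The mean covered length over the replicates was 188087 bp ± 20812 (SD, n = 2). The HoxB domain (chromosome 11, 96230914 to 96382691) was 152 kb long and 79.1% ± 5.80 covered. The HoxA domain (chromosome 6, 52146387 to 52285007) was 139 kb long and 89.7% ± 3.19 covered, and the HoxD domain (chromosome 2, 74642599 to 74770796), which also held Evx2, was 128 kb long and 86.8% ± 3.11 covered (SD, n = 2 each). Hoxb13 lay apart with Ttll6 in a domain of 79.9 kb (chromosome 11, 96133285 to 96213174).

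Next in length were domains with few or no genes. A domain of 103 kb on chromosome X (99152125 to 99254877) held no annotated gene. Its nearest protein-coding gene was Efnb1, an ephrin ligand, 3134 bp away. The replicates differed there, with 47.6% of the domain covered in replicate 1 and 14.4% in replicate 2, and the highest fold of a replicated peak in it was 5.65. That it held no gene depended on the setting. With the peaks of replicate 1 alone, the longest domain (99125586 to 99307300) held all of Efnb1. With a merging gap of 10000 bp, the longest domain (99152125 to 99692009) held all of Pja1. The domain at Nfix (chromosome 8, 84731190 to 84814900), a nuclear factor gene, was 83.7 kb long and 59.3% ± 8.75 covered. Domains over Wnt3a and Wnt9a (chromosome 11, 59239194 to 59315877, 76.7 kb), over Zic1 and Zic4 (chromosome 9, 91347663 to 91420808, 73.1 kb) and over the Polycomb subunit genes Cbx4 and Cbx8 (chromosome 11, 119033228 to 119101783, 68.6 kb) followed. The first was 72.3% covered in replicate 1 and 53.8% in replicate 2, and the other two were 78.6% ± 2.29 and 65.7% ± 9.34 covered (SD, n = 2 each).

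**Figure D2:**
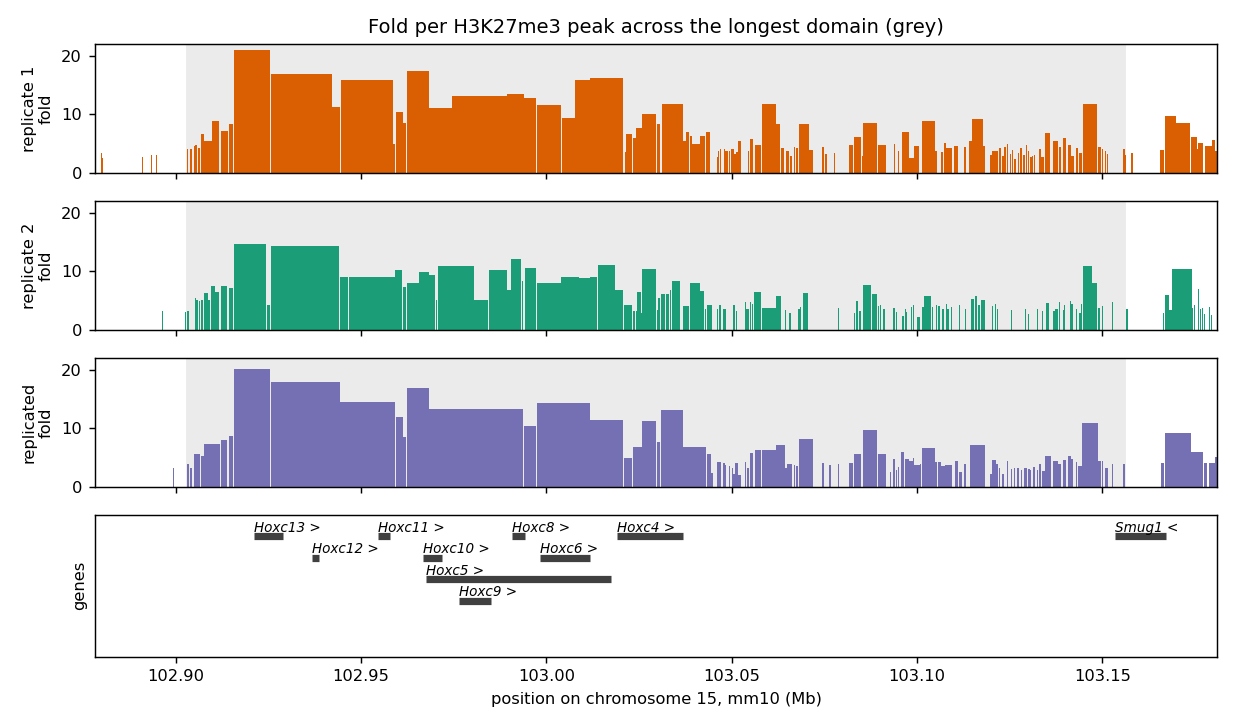
Peaks on chromosome 15 of mm10 around the HoxC cluster, with position in Mb on the horizontal axis and the fold given for each peak on the vertical axis, for replicate 1, replicate 2 and the replicated list. Grey marks the domain from 102903094 to 103156051, and black bars with arrowheads the genes and their strands. The highest fold in the domain was 14.6 in replicate 2 and 20.0 in the replicated list, in both cases near Hoxc13.

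Peaks lay at promoters far more often than random placement would put them. Of the replicated peaks, 12.8% had their midpoint within 1000 bp of the 5' end of a protein-coding gene, against 1.67% of shuffled peaks, a ratio of 7.67. Exons held 8.84% of the midpoints against 3.45% in shuffles. Introns held 35.5% against 36.1%, and intergenic sequence 42.9% against 58.8%. The promoter share was 8.32% in replicate 1 and 15.5% in replicate 2 (mean 11.9% ± 5.07, SD, n = 2).

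The mark was spread unevenly over the chromosomes. Chromosome 11 had the largest covered length, 24.3 kb per Mb ± 9.56 (SD, n = 2), followed by chromosome 19 with 20.0 ± 6.75 and chromosome 4 with 16.6 ± 6.72. Chromosome 3 had the smallest of the autosomes, 6.67 ± 2.25. On chromosome X the replicates stood furthest apart, with 20.7 kb per Mb in replicate 1 and 6.36 in replicate 2. The replicated list had 4414 peaks on chromosome X, 2.05 times as many per Mb as on the autosomes, with narrower peaks on X (median 327 bp against 433 bp). The ratio of covered bp per Mb was 0.971 in the replicated list, 1.32 in replicate 1 and 0.695 in replicate 2, so its direction turned with the replicate. No list held a peak on chromosome Y.

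**Figure D3:**
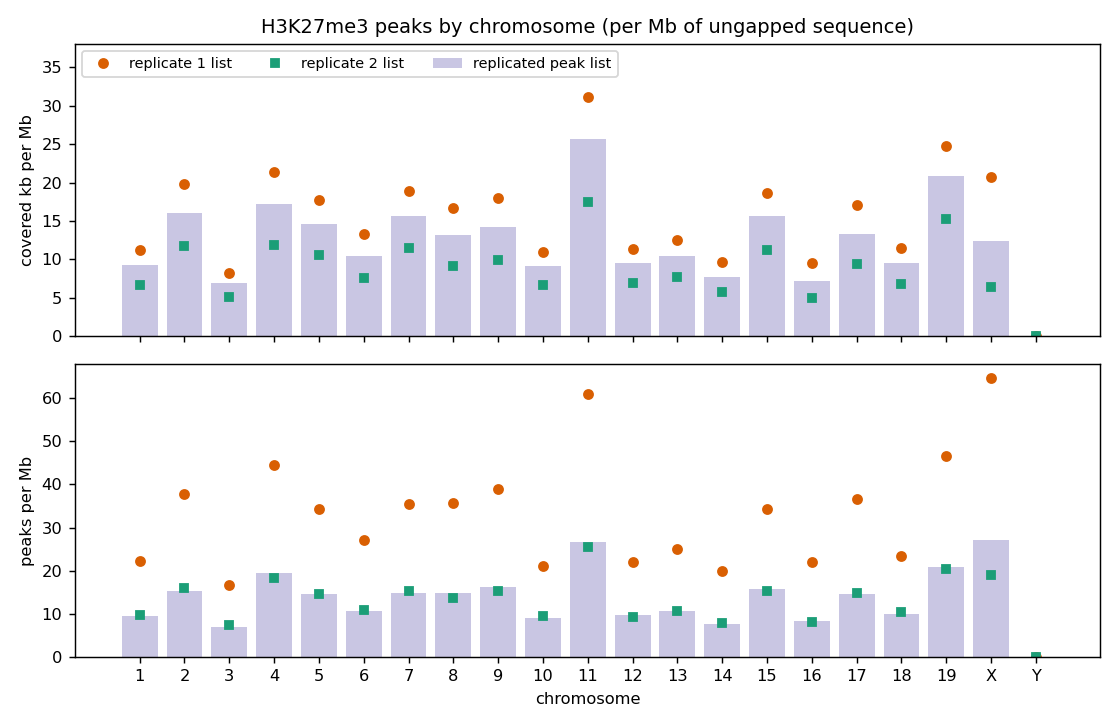
Covered kb per Mb (top) and peaks per Mb (bottom) of ungapped sequence for each chromosome. Bars give the replicated list, circles replicate 1 and squares replicate 2, which both lie at 0 on chromosome Y. Replicate 1 lies above replicate 2 on every other chromosome, and on X the covered length was 20.7 kb per Mb in replicate 1 and 6.36 in replicate 2.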

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

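Limiting the peak counts to −log10 q of at least 2, moving peaks by 50 to 500 kb, and leaving Cdkn2a and Cdkn2b out of the imprinted list, were chosen after seeing the data. The 10 lists marked more often and the 2 marked less often became 9 to 12 and 2 to 3 under the alternatives run. The share of marked promoters stayed between 19.2% and 25.2%. Of the alternative values for the main results, 180 counted as unchanged, 13 moved further, 7 newly passed the threshold, 1 no longer passed it and 1 reversed. The rule differed by result and used the threshold, the replicate SD, an exact binomial interval over peaks or a ratio to the main value. No paired analysis was possible because there is 1 group. The cause of the changes below was not tested, except where the setting names it.

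With −log10 q of at least 2, replicate 1 had 51604 peaks and replicate 2 had 16700, 85.0% of the pooled peaks were kept as replicated, and 46.9% of those overlapped both replicates. Of all replicated peaks, without the limit on q, 50.5% overlapped both by at least 1 bp. By the same exact test, mature liver genes passed the threshold as marked less often with the 2500 bp window (6.25%, adjusted p = 0.0301) and with 200 bp of overlap (3.125%, adjusted p = 0.0187), and leaving out each replicate gave 3.125% to 18.75%, but they did not pass against CpG-matched lists, whose mean was 9.89% (adjusted p = 0.772, permutation). Polycomb genes passed with the 2500 bp window (41.2%). Blood stem cell, megakaryocyte and myeloid genes passed against CpG-matched lists, whose mean was 18.3%, and gave 33.3% to 43.3% when each replicate was left out. Lymphoid genes gave 30% to 43.3%. Clustered protocadherin genes did not pass against CpG-matched lists, whose mean was 28.1%, and 1 gene per 100 kb stretch left 3 genes, with 0% marked.

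Domains of at least 10 kb numbered 541 with a gap of 1000 bp, 1912 with a gap of 10000 bp, and 651 to 1756 when each replicate was left out. The bp covered in the longest domain were 137749 with a gap of 1000 bp (HoxC) and 184886 with 10000 bp (chromosome X). Those covered in the HoxC domain of the replicated list were 173371 to 202803 when each replicate was left out. With the 2500 bp window 25.8% of peaks lay at promoters. The ratio of peaks per Mb on X over autosomes was 1.45 to 2.06 when each replicate was left out. Of the values for single named genes, 349 stayed within the replicate SD and 43 did not. The depth of the libraries, not in the lists, limits which weak peaks could be called.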

Other observations

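Gene families outside the fixed lists were marked as well. Of 268 families of at least 10 genes that share the start of a symbol, chosen after the lists had been analysed, 211 have no gene in a list. Among these, 20 were marked more often than other genes and 19 less often (2-sided Fisher's exact test, Benjamini-Hochberg adjusted over the 268). Neither matching on promoter CpG content nor thinning to 1 gene per 100000 bp stretch was done for the families. Serotonin receptor genes (Htr) were marked at 13 of 14 promoters (adjusted p = 6.9e-07, exact test), synaptotagmins (Syt) at 14 of 17, semaphorins (Sema), which guide axons, at 16 of 20, and non-clustered protocadherins (Pcdh) at 12 of 12. Collagen genes (Col), 3 of which stand in the mesenchyme list, were marked at 30 of 45 (Fisher's exact test, adjusted p = 6.5e-09), with 73.3% in replicate 1 and 57.8% in replicate 2. Vomeronasal receptor genes (Vmn) were marked at 0 of 330, keratin-associated protein genes (Krtap) at 0 of 57 and mitochondrial ribosomal protein genes (Mrpl) at 0 of 49. Zinc finger genes (Zfp), 1 of them in a list, were marked at 40 of 394, or 10.2%.

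Promoters of other kinds of transcript were marked less often than the protein-coding 21.3%. Antisense RNA genes were marked at 17.4% of 2959 promoters, and 69.1% of the marked ones had a marked protein-coding 5' end within 10000 bp. Long intergenic RNA genes were marked at 8.80% of 5854 (13.3% in replicate 1 and 7.57% in replicate 2) and microRNA genes at 8.22% of 2202. No test was made between these kinds. In the tests of the next paragraphs, those of the background level before scaling, of peaks moved by 50 to 500 kb, of stronger summits in either pattern and of the X peaks of −log10 q of at least 2 were chosen only after the result was seen.

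Developmental regulators were marked more often than other genes, and the tables argue against both technical explanations tried. In the HOX list, the lists of neural, of heart, muscle and limb and of pancreas, gut and lung factors, and the ligand list, at least 87.5% of promoters were marked. Random lists matched on promoter CpG content had means of 26.0% to 28.5%, and the lowest of these 5 lists stood at percentile 100 of 10000 such lists. With 1 gene kept per 100000 bp stretch the largest adjusted p of the 5 was 0.0040 (Fisher's exact test, HOX, 4 genes). The matching used the ratio of observed to expected CpG within 1000 bp of the 5' end, so the length of CpG-rich stretches was not matched. No other explanation was tested, since there is 1 group.

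Replicate 1 had 2.49 times as many peaks as replicate 2, and a candidate explanation is how the replicates were scaled against their controls. A Poisson tail on the height of the peak, with the fold as (height + 1) / (background + 1), gave back the −log10 p of 100% of peaks in both lists within 0.001 when heights were whole numbers times 1 in replicate 1 and times 0.541 in replicate 2. The height of each peak and the scale were chosen for the best match. At a wider tolerance, scales not in a simple ratio to these matched at most 40.3% of a sample of peaks in replicate 1 and 35.3% in replicate 2. The background before that scaling was 2.14 in replicate 1 and 2.36 in replicate 2 (ratio 0.908), which argues against a deeper ChIP library in replicate 1. At shared peaks the median ratio of replicate 1 over replicate 2 was 1.69 for −log10 p and 1.18 for fold. Each replicate 2 peak was paired with the overlapping replicate 1 peak of highest −log10 p, a choice that can raise both ratios. The heights and background of replicate 1 were then multiplied by 0.595, the background as used in replicate 2 over that in replicate 1. With this factor, replicate 1 would have 1.36, 0.921, 0.835, 0.850 and 0.849 times as many peaks as replicate 2 of −log10 p of at least 3, 4, 6, 8 and 10. Without it the values were 2.84, 2.68, 2.24, 2.24 and 1.89 times. The test set before used p of 0.01, where 77018 peaks would still pass. This was 2.24 times the number of replicate 2 and missed the limit set for it. That count was set aside because only 1.55% of the summits of replicate 1 have a −log10 p under 2.5, a reason not in the test as set. Of the 62187 unshared peaks of replicate 1, all but 40.0% lay within 10000 bp of a replicate 2 peak. This share was 6.16 times that of shuffled peaks (9.74%) and 2.32 times that of peaks moved by 50 to 500 kb (25.9%). The values argue against scattered background as a source of all these peaks. They say nothing of the 40.0%, and they cannot tell which of the near peaks lie there through local peak density, as 25.9% of the moved peaks did. Whether the scaling of replicate 2 alone makes up the gap stays open, and the size of its control is not known from the lists.

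Chromosome X had 2.05 times as many replicated peaks per Mb as the autosomes, and the excess sat in peaks of weaker summits: the ratio was 1.62 with −log10 q of at least 2 but 0.760 with −log10 p of at least 6. Lower effective depth of replicate 2 stays open for its smaller X excess. At p of 0.01, the cutoff set before, replicate 1 with the factor of 0.595 had a ratio of 2.17 against 1.45 in replicate 2. This missed the limit of 1.2 times set before the test, but the cutoff was set aside for the reason given above. At −log10 p of at least 6 the factor moved the ratio from 1.36 to 0.519 against 0.433, and at least 3 from 2.07 to 1.58 against 1.09. With at least 3, 4, 6, 8 or 10 the ratio of replicate 1 stayed above that of replicate 2, by at most 1.51 times, and came within the limit at 6 only. More X copies in the ChIP than in the control cannot be told apart from a real excess, because the ratio in gene-dense over gene-poor 1 Mb bins was 1.03 with a 95% bootstrap interval of 0.551 to 2.25. Silencing of 1 X chromosome in female embryos may contribute, but 8 genes known to escape it were covered, with 5000 bp on each side, over 3.07% against 6.66% in CpG-matched X-linked genes, at percentile 20.5 of random sets, which 8 genes cannot decide.

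The rule behind the replicated list was only partly seen in the lists. All 17768 pooled peaks that shared at least 50% of either peak's length with a peak in both replicates' lists were kept, and 18218 others, 50.6% of the kept peaks, were kept without it.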
